A study of Homo sapiens with 9 samples.

How the data were processed

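RNA was measured in 3 libraries of the human breast adenocarcinoma line MCF7, transfected with a non-targeting control siRNA (siCONTROL), an siRNA against GATA3 (siGATA3) or an siRNA against TCF7L2 (siTCF7L2), with 1 library per group. Per the labels' protocols, cells of passage 7 received 50 nM siRNA with Lipofectamine, the medium was replaced after 12 hours, the cells grew for another 36 hours, and Illumina TruSeq RNA libraries were amplified for 12 cycles. The kit does not mark strand. Histone marks were measured by ChIP-seq and are held as 6 peak lists, H3K4me1, H3K27ac, H3K27me3 and H3K9me3 in MCF7 of passage 5 and H3K4me1 and H3K27ac in the human colorectal cancer line HCT116 of passage 9. Per the labels, each MCF7 list stands for 3 replicates, except H3K27ac with 2, and each HCT116 list stands for 2. The lists hold no value per replicate, so none has a replicate spread.

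Per the submitters' processing notes, the genome build is hg19 and TopHat was used; its version and settings are not given in the sources used here. Per the file headers, the expression files hold an FPKM value per gene (fragments per kilobase per M fragments, M for mega), with the lower and upper bound of an interval and a quantification status, in the format of the Cufflinks gene tracking table. The deposited FPKM values were some 16492.8 times larger than fragments per kilobase per M fragments computed from the same files, so every value was divided by that constant, which is common to the 3 libraries and leaves all ratios as deposited. The quotients are called FPKM equivalents. The constant came from protein-coding genes with 1 annotated transcript, of which 476, 473 and 479 in siCONTROL, siGATA3 and siTCF7L2 had at least 100 implied fragments. Implied fragments are the number whose Poisson counting error gives the deposited interval. They were taken from genes with status OK, because the intervals of genes with status FAIL give no usable number. The implied totals were 24.9 M, 24.8 M and 26.6 M fragments for siCONTROL, siGATA3 and siTCF7L2. Of the genes with few implied fragments, 59.8%, 60.6% and 59.9% lay within 0.02 of a whole number. The value of 1 fragment relative to siCONTROL was 1.02 in siGATA3 and 0.948 in siTCF7L2, while the upper quartile of implied fragments was 0.980 and 1.05 of that in siCONTROL. The design had assumed FPKM on its usual scale, and the size filter was therefore applied to the FPKM equivalents. Intervals cover counting error within a library only, and PCR copies are not independent molecules.

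Each expression file holds 24921 genes and loci in a different order, and the files were joined on gene and locus. Status was OK for 24534, 24539 and 24532 of them. Gene starts in the files count from 0 and were written counting from 1. Of 19357 symbols found once in the GENCODE annotation lifted to GRCh37 (hg19), 98.3% overlapped the annotated gene on the same chromosome.

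The peak files are GFF lists whose source field names Sole-search, per the file headers. Each peak carries a deposited whole-number score whose meaning the files do not state, so scores were used only to rank peaks within a list. Peak edges lie on a grid of 30 bp. The version and threshold of the peak caller are not given in the sources used here. The source field of the MCF7 H3K27me3 list names a single replicate A, although its label names 3 replicates. The source field of the list labelled HCT116 H3K4me1 names H3K27ac, and that of the list labelled HCT116 H3K27ac names H3K4me1. Lists follow their labels here and are called the lists labelled H3K4me1 and H3K27ac.

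A gene was tested in a comparison when its mean over the 3 libraries was at least 1 FPKM equivalent, its status was OK in both libraries and its symbol was not that of a small RNA. It was called higher or lower when the ratio after adding 1 to each value was at least 1.5-fold and the deposited intervals of both libraries did not overlap. With 1 library per group there is no replicate check and no p-value across genes is given; the calls compare these libraries. On simulated counts for siGATA3 against siCONTROL with 200 genes changed, not all of which passed the minimum, 12159 genes were tested and the rule called 49 of 50 genes raised 2-fold, 45 of 50 lowered 2-fold, 49 of 50 raised 3-fold and 50 of 50 lowered 3-fold. It called 2 of 11960 unchanged genes there, and 2 of 12159 for siTCF7L2 against siCONTROL. The simulated libraries differed by counting error only, so these rates leave out differences between cultures and preparations.

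A total of 26 gene lists were fixed before the data were examined. For each, the median log2 ratio of the tested members was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. In simulated libraries, 12 of 200 unshifted lists fell outside the central 95%. The named genes are both siRNA targets, the 10 highest and the 10 lowest ratios among called genes of each comparison, and up to 4 called members of each list. List members that were not called are given as examples with values. For ChIP they are the genes of the luminal breast and colon lists and the 3 highest-scoring and 3 widest peaks of each list.

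The responses to both siRNAs share the siCONTROL library, so their overlap and covariance stand beside 100 simulated sets of unchanged libraries with noise from the deposited intervals. Peak lists were compared by the share of peaks overlapping by at least 1 bp, beside 1000 circular shifts along each chromosome, with one-sided permutation p in both directions. The smallest p this can give is 0.000999, 1 in 1001, and a p under 0.025 on either side counted as a departure. Gene starts are those of 20048 protein-coding genes on 23 chromosomes, with a window of 2 kb. Genes called in a knockdown were compared with 10000 random lists matched on expression for marks within 10 kb of the gene span. Families were marked when a peak lay within 2 kb of the gene span. Intervals of shares are 95% Wilson intervals. Correlations across chromosomes used 100000 permutations.

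Alternatives tried were pseudocounts of 0.1 and 0.5, no minimum or a minimum of 5 FPKM equivalents, ratios centred on the median, equal upper quartiles, a fold of 2, calls without intervals, small RNAs kept and values summed per symbol. For peaks they were overlap of 50% of the shorter peak, the upper-scoring part of each list, equal list lengths, autosomes alone, windows of 1, 5 and 50 kb and exchanged HCT116 lists. Leaving out genes that overlap another gene, matching random lists on gene length, and filtering and matching gene lists on the siCONTROL value alone were added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.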

Results

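The series measured gene expression in MCF7 breast cancer cells after knockdown of GATA3, a transcription factor of the luminal breast lineage, or of TCF7L2, a DNA-binding partner of beta-catenin in Wnt signalling. It also mapped histone marks in MCF7 and in HCT116 colorectal cancer cells. The expression data are 1 library each of siCONTROL, siGATA3 and siTCF7L2, with 24.9 M, 24.8 M and 26.6 M implied fragments (M for mega). The ChIP data are 4 peak lists from MCF7 and 2 from HCT116. With 1 library per group no expression difference has a replicate check. Values are FPKM equivalents.

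GATA3 (10:8096667-8117164, hg19) fell to 66.2% of its control level in the siGATA3 library, from 398 to 263, a log2 ratio of -0.59. Its level in the siTCF7L2 library was 397. TCF7L2 (10:114710009-114927436) was at 3.68 in siCONTROL and 3.45 in siGATA3. In siTCF7L2 it was at 2.38, which is 64.6% of control. Its intervals did not overlap, but the log2 ratio of -0.47 after adding 1 did not reach 1.5-fold; with a pseudocount of 0.1 it was -0.61 and passed. Each target was thus lowest in the library labelled with its siRNA.

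The comparison of siGATA3 with siCONTROL asks which genes differ with the siRNA against GATA3 in MCF7. GATA3 RNA was still at 66.2% of control, and the series holds a single duplex and transfection. Loss of GATA3 and other effects of the duplex therefore cannot be told apart for any gene below. Interferon-stimulated genes rose together: 27 of the 28 tested members of the interferon list were higher, with a median log2 ratio of 1.86, above all 10000 matched random lists. The minimum on the mean of the libraries lets in genes by their rise; of the 21 members already at 1 or more in siCONTROL, 20 were higher, with a median of 1.81, again above all random lists, a filter chosen after the data were seen. IFIT1, an antiviral RNA-binding protein, rose from 0.705 to 61.1 (log2 5.19). IFI6 rose from 31.7 to 407 (3.64), and the RNA-sensing synthetases OAS2 and OAS1 rose from 0.314 to 15.2 (3.63) and from 1.85 to 26.2 (3.26). Genes of the cell cycle and DNA replication moved the other way, with 16 of 28 lower, none higher and a median of -0.62, below all matched random lists.

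The remaining genes with the largest increases were also interferon-induced. IFI27 rose from 8.52 to 90.4 (log2 3.26), the antiviral GTPase MX1 from 0.677 to 8.89 (2.56), and the virion-tethering protein BST2 from 2.33 to 18.1 (2.52). IRF9, the DNA-binding part of the interferon-activated complex, rose from 10.3 to 61.2 (2.46). The ubiquitin-like modifier ISG15 rose from 66.0 to 341 (2.35) and the helicase DDX60 from 0.168 to 4.43 (2.22). HERC5, at 1.23 and 1.77, was the tested member that did not pass. Of the 35 members 7 were not tested, 6 under the minimum and STAT2 for its status, and all 7 had ratios above 0. Of the 75 genes at least 2-fold higher, 26 were on the interferon list. The 34 members of that list with status OK in every library held 0.0571% of implied fragments in siCONTROL, 0.243% in siGATA3 and 0.0569% in siTCF7L2.

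Among proliferation genes, MYBL2, a cell-cycle transcription factor, fell from 96.8 to 48.5 (log2 -0.98). E2F1 fell to 11.4 (-0.76), thymidine kinase TK1 from 102 to 60.5 (-0.74) and cyclin CCNA2 from 41.0 to 24.6 (-0.71); the locus of CCNA2 overlaps another gene. The 12 members that did not pass all had ratios below 0, such as the replication clamp PCNA, which overlaps another gene, at 166 and 124 (-0.41), CCNB1 at 116 and 81.2 (-0.51) and MKI67 at 64.8 and 46.1 (-0.48).

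The luminal list split. Of 24 tested members 4 rose, 2 fell and 18 did not pass, with a median of 0.13 at percentile 99.4 of matched lists. The secreted trefoil factor TFF3 rose from 49.3 to 172 (log2 1.78), the progesterone receptor PGR from 16.9 to 33.0 (0.92), NAT1 from 6.45 to 12.7 (0.88) and the ETS factor SPDEF from 94.4 to 153 (0.69). The carbonic anhydrase CA12 fell from 74.8 to 32.5 (-1.18) and ELF3 from 37.7 to 22.1 (-0.74). The estrogen receptor ESR1, at 103 and 110, and its pioneer factor FOXA1, at 137 and 132, did not pass. Estrogen-induced genes had a median of -0.15 at percentile 0.195, with KRT13 (-0.99) and STC2 (-0.92) lower, PGR higher and 18 of 21 not passing. Among basal markers OXTR (1.43) and ACTA2 (0.60, uncertain because it overlaps FAS) rose, CAV1 (-0.72) and LAMB3 (-0.67) fell and 11 of 15 did not pass, with a median of 0.10 at percentile 86.0.

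Wnt target genes had a median of -0.11 at percentile 2.94. Of 18 tested, 4 fell and none rose. The transcription factor MYC fell from 17.3 to 7.38 (log2 -1.13), the receptor antagonist BAMBI from 26.4 to 12.0 (-1.08), SOX9 from 4.22 to 2.08 (-0.76) and JUN from 11.9 to 6.62 (-0.76). CCND1, at 287 and 195 (-0.55), did not pass. Wnt pathway components had a median of -0.06 at percentile 6.56, with the corepressor TLE3 (-0.86) and the receptor FZD8 (-0.59) lower and 28 of 30 not passing. All 8 tested Notch targets had ratios below 0, with a median of -0.35 at percentile 0.0700; HES1 fell from 20.2 to 11.1 (-0.81).

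In all, 504 of 12225 tested genes were called, 248 higher and 256 lower, and at 2-fold 75 were higher and 19 lower. Large decreases outside the lists were ITGB6, an integrin subunit, from 4.06 to 0.715 (log2 -1.56), the kallikrein protease KLK6 from 12.4 to 4.29 (-1.34), the kinase SIK1 from 6.21 to 2.25 (-1.15) and the clotting inhibitor TFPI from 13.5 to 5.75 (-1.11). PCNA-AS1 (-3.29), H3F3A (-2.34), EEF1E1-MUTED (-2.31) and SCLY (-1.56) overlap other genes, and H3F3A has near-identical copies, so their values are uncertain in a kit that does not mark strand. Of the called genes, 99 overlap another gene.

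**Figure D1:**
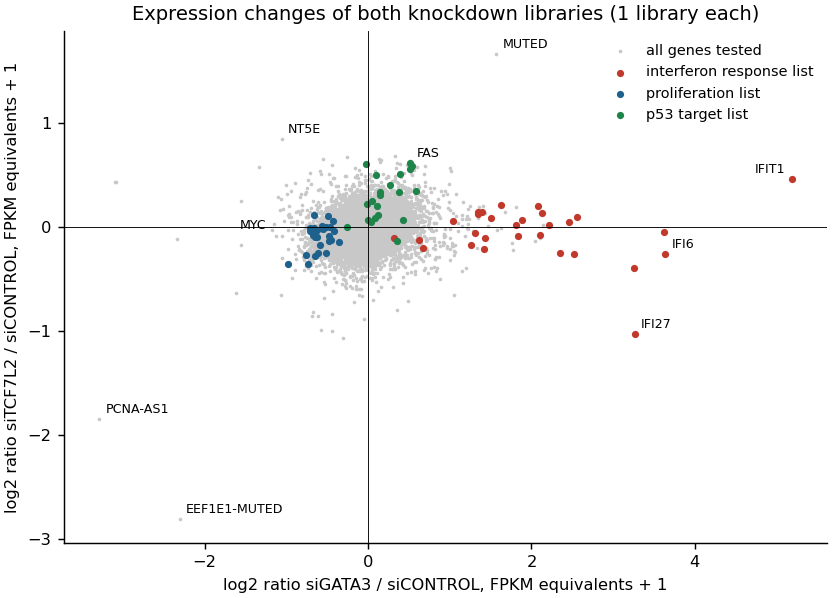
Log2 ratio of siGATA3 over siCONTROL (horizontal) against siTCF7L2 over siCONTROL (vertical) for each tested gene, 1 library per group, both after adding 1 to the FPKM equivalents. Interferon genes (red) extend to 5.19 on the horizontal axis, with a median of -0.01 on the vertical axis.

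The comparison of siTCF7L2 with siCONTROL asks which genes differ with the siRNA against TCF7L2. Few genes were called: 37 of 12220, 15 higher and 22 lower. TCF7L2 RNA was still at 64.6% of control, so this count does not show how many genes depend on TCF7L2. The ecto-nucleotidase NT5E rose from 3.08 to 6.33 (log2 0.85) and the cell-cycle kinase CDK6 from 4.10 to 7.18 (0.68). The recombinase RAD51 fell from 13.7 to 7.14 (-0.85) and interferon-induced IFI27 from 8.52 to 3.65 (-1.03). Targets of p53 had a median of 0.28, above all matched random lists, with 3 of 20 higher; against siGATA3 the median was 0.10, inside the central 95%, with 1 of 20 higher.

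The p53 targets that rose were the death receptor FAS, whose locus overlaps another gene, from 3.42 to 5.79 (log2 0.62), TP53INP1 from 14.7 to 23 (0.61) and the stress-response gene SESN1 from 15.0 to 23.1 (0.59). The p53 ubiquitin ligase MDM2, at 46.5 and 62.2 (0.41), and the antiproliferative gene BTG2, at 24.5 and 35.5 (0.52), did not pass. In siGATA3, FAS was at 5.30 and SESN1 at 22.1, close to their siTCF7L2 levels, while TP53INP1 was at 14.4, so part of the difference from the single siCONTROL library is shared by both knockdown libraries. The cell-cycle inhibitor CDKN1A, at 121 and 178, was not tested because its status in siTCF7L2 was FAIL. Wnt targets had a median of 0.10 at percentile 99.3 with none of 18 called, and at a minimum of 5 FPKM equivalents the median of 0.0936 lay inside the central 95%; AXIN2, a feedback inhibitor of Wnt signalling, was at 2.24 and 3.55 (0.49), and CCND1 at 287 and 366 (0.35). Wnt pathway components had a median of 0.02 at percentile 66.7 and none called.

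Other called genes that overlap no other gene included SHISA2 (log2 0.68), the sodium channel subunit SCN1B (0.66) and FHL2 (0.65), which rose, and RPPH1, the RNA of RNase P (-1.07), and LOC100144603 (-0.84), which fell. Called genes that do overlap another gene, and are uncertain, included MUTED (1.66), INHBA (0.65), CDSN (0.62), EEF1E1-MUTED (-2.82), PCNA-AS1 (-1.85), NEDD8-MDP1 (-0.99), SMN2 (-0.88), PMCH (-0.86) and SERF2-C15ORF63 (-0.81). SMN2 also has a near-identical copy, and another locus named SMN2 was called lower as well (-0.59). Both loci are counted separately in the calls and in the shares of marks below. Genes that overlap another gene made up 43.2% of the calls and 20.3% of the genes tested.

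For the remaining lists with siTCF7L2, basal markers had a median of 0.15 (percentile 99.9), YAP targets 0.11 (98.4) and proliferation genes -0.07 (0.970), with none called. With the filter on siCONTROL alone, YAP targets were at 0.0945 (96.4), inside the central 95%. The medians were -0.06 for luminal genes (3.16) and -0.05 for estrogen-induced genes (7.14), also with none called. The interferon list had a median of -0.01 at percentile 28.7, with IFI27 as the called member; with the filter on siCONTROL alone it was -0.0862, below the central 95%.

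**Figure D2:**
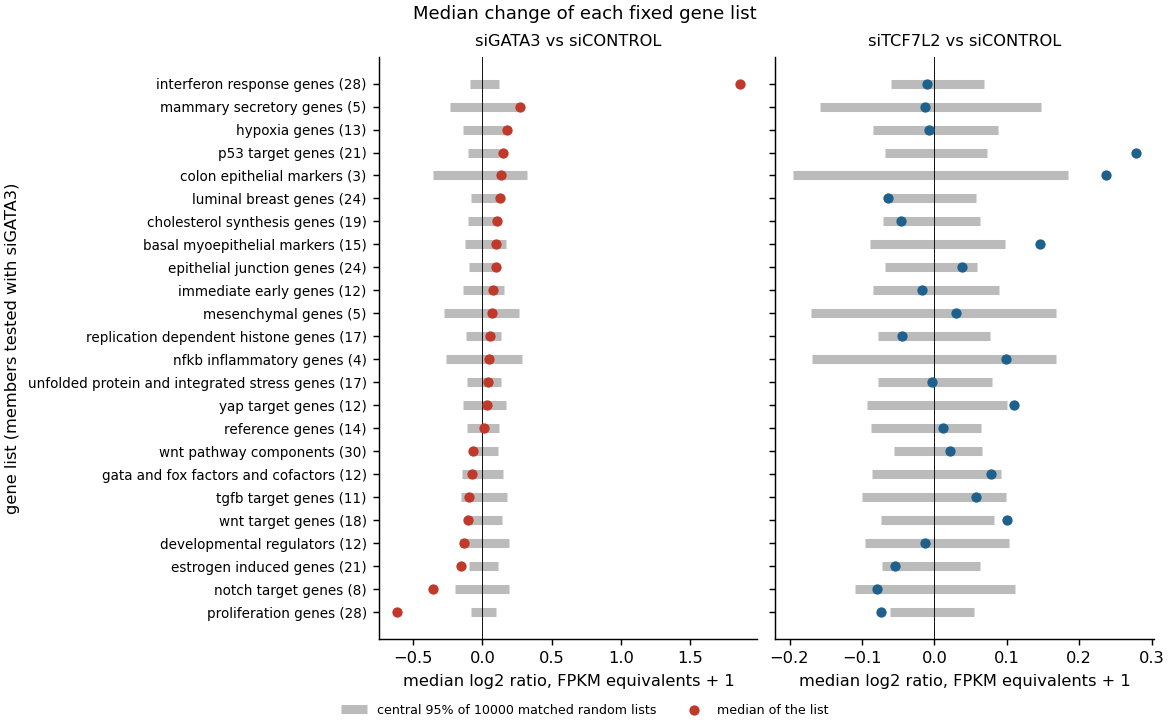
Median log2 ratio of each gene list (points) and the central 95% of 10000 matched random lists (grey), for siGATA3 (left) and siTCF7L2 (right), with the members tested with siGATA3 in brackets. The interferon list lies at 1.86 and the proliferation list at -0.62 with siGATA3.

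Set directly against siGATA3, the siTCF7L2 library had 235 genes higher and 302 lower of 12213. KLK6 (log2 1.92), NT5E (1.90), ITGB6 (1.81), the hormone STC1 (1.41), TFPI (1.39), the sulfate-activating enzyme PAPSS2 (1.33), GPRC5A (1.31) and OLFML3 (1.31) were higher. H3F3A (2.23) and SCLY (1.39) were also called but overlap other genes. The lowest were interferon-induced: IFIT1 (-4.72), IFI27 (-4.30), IFI6 (-3.90), OAS2 (-3.67), OAS1 (-3.65), BST2 (-2.78), ISG15 (-2.60), MX1 (-2.46), IRF9 (-2.40) and the ISG15-conjugating enzyme UBE2L6 (-2.21).

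Both knockdowns called 7 genes in the same direction among 12170 tested in both. MUTED and TNFRSF10C were higher, and EEF1E1-MUTED, PCNA-AS1, PLA2G10, RAD51 and SERF2-C15ORF63 lower. All but PLA2G10 and RAD51 overlap another gene. MUTED and EEF1E1-MUTED share their start (6:8013800), so this pair may not be independent. IFI27 and RLN2 were higher with siGATA3 and lower with siTCF7L2, and NT5E the reverse. TNFRSF10C, PLA2G10 and RLN2 are named because the counts are small, after their values were seen. Independent lists of these sizes would share 0.303 genes higher and 0.461 lower, and unchanged libraries with a shared control shared 0.1 on average. The covariance of the log2 ratios was 0.0103 against 0.00394 in the simulations, a difference of 0.00639. The correlation was 0.221 against 0.496, and 60.7% of genes had the same sign against 66.7%. Part or all of any excess may come from the shared control library, which cannot be split. The simulations held counting error only, so a deviation of that culture or preparation would add to the covariance and the shared calls.

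The MCF7 marks were compared with each other to see which regions carry active and which carry repressive chromatin. Of the 20760 H3K4me1 peaks, a mark of enhancers, 64.3% overlapped H3K27ac, a mark of active enhancers and promoters, against 4.42% for shifted positions, 14.5-fold. H3K27ac avoided the Polycomb mark H3K27me3: 2.84% of its 32517 peaks overlapped it against 7.08% for shifted positions, a ratio of 0.402. H3K27me3 overlapped the heterochromatin mark H3K9me3 1.33-fold above shifted positions, at 6.21% of its 48989 peaks. Both of these lists had wide peaks at the same places, such as DOK5 and TBX4. The shifts cannot tell a relation between the marks from a signal common to a region, such as copy number, which was not measured.

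In the other directions, 33.5% of H3K27ac peaks overlapped H3K4me1 (12.8-fold) and 2.04% of H3K27me3 peaks overlapped H3K27ac (0.412). These relations and the ones above with a ratio over 10 or under 0.5 had a permutation p of 0.000999, the smallest that the shifts can give. H3K27me3 on H3K9me3 had a permutation p of 0.005, H3K9me3 on H3K4me1 was at 1.35-fold (permutation p 0.012) and H3K27ac on H3K9me3 at 0.871 (0.018 by permutation, lower side). The reverse of the former, H3K9me3 on H3K27me3, was at 1.36-fold with a permutation p of 0.028, which did not pass. H3K4me1 on H3K27me3 (1.04), its reverse (1.03), H3K4me1 on H3K9me3 (1.24) and H3K9me3 on H3K27ac (0.908) did not pass either. The lists covered 29 Mb for H3K4me1, 75.9 Mb for H3K27ac, 118 Mb for H3K27me3 and 57.5 Mb for the 30398 peaks of H3K9me3. Median widths were 1080, 1560, 1320 and 1140 bp.

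By score, the top H3K4me1 peak lay in GRHL2, a regulator of epithelial genes (8:102613590-102624689, score 63), followed by NOTCH2 and CUEDC1. The top H3K27ac peak covered 62940 bp at ESR1 (6:151968270-152031209, score 143); the next were at 3:161118120-161145539 near SPTSSB and in DSCAM. The widest H3K27ac peaks were at the growth factor receptor gene IGF1R (67860 bp), ESR1 and the estrogen-induced gene GREB1 (61890 bp), and the widest H3K4me1 peaks were at IGF1R (31080 bp), TMEM64 and GRHL2. For H3K27me3 the top and widest peak was 378780 bp at DOK5 (20:52992060-53370839, score 194), with further wide peaks at ADAMTS9 and CADPS and high scores at 18:106200-111959 and TBX4. H3K9me3 was widest at 17:59285280-59643629 over BCAS3, TBX2 and TBX4 (358350 bp), at DOK5 and at ZNF217, and scored highest at 18:105720-112439, BRIP1 and BCAS1. Peaks of H3K27me3 and H3K9me3 lay at nearly the same positions at DOK5 and on 18, and ended at the same base at TBX4. The region on 18 was also the top-scoring peak of the list labelled HCT116 H3K27ac (18:106140-112259). No copy number was measured, and whether these peaks mark repressive chromatin was not tested.

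GATA3 itself lay under a 48420 bp H3K27ac peak in MCF7 (10:8086500-8134919) with 6 H3K4me1 peaks and no H3K27me3 or H3K9me3 peak within 10 kb. At TCF7L2, MCF7 had 4 H3K27ac peaks covering 7.86 kb and no peak of the other marks, while the HCT116 lists labelled H3K4me1 and H3K27ac had 38 and 27 peaks. These loci were chosen after the lists were seen.

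H3K27ac sat at gene starts, and H3K4me1 did not. H3K27ac lay within 2 kb of 48.8% of 20048 protein-coding gene starts, and 28.3% of its peaks were there. H3K4me1 marked 9.77% of starts (9.52% of its peaks), H3K27me3 9.35% (4.98%) and H3K9me3 3.37% (2.54%). Coverage at the start itself was 40.0% for H3K27ac against 9.57% at 1.5 to 2.5 kb away, a ratio of 4.18. For H3K4me1 it was 1.03% against 3.20%, a ratio of 0.323.

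The HCT116 lists did not follow the MCF7 lists of the same name at gene starts. The list labelled H3K4me1 covered 55.9% of starts against 17.5% at the flank, a ratio of 3.20, and the list labelled H3K27ac covered 13.4% against 21.9%, a ratio of 0.615. The former had 30.8% and the latter 26.7% of peaks within 2 kb of a start, and they marked 60.2% and 57.6% of starts.

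**Figure D3:**
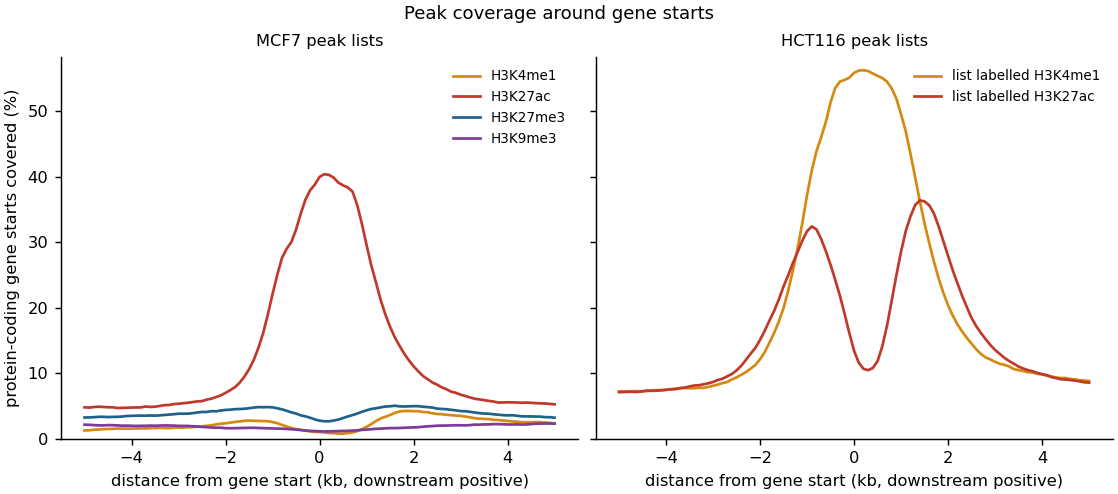
Share of protein-coding gene starts covered by peaks at each distance from the start (kb), for the MCF7 lists (left) and the HCT116 lists under their labels (right). At the start, MCF7 H3K27ac covers 40.0% and H3K4me1 1.03%, while the HCT116 list labelled H3K4me1 covers 55.9%.

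Between cell lines, 29.1% of MCF7 H3K4me1 peaks overlapped the list labelled HCT116 H3K4me1, 5.88-fold above shifted positions, and 14.4% the other way round (5.52-fold). Of MCF7 H3K27ac peaks, 50.4% overlapped the list labelled HCT116 H3K27ac (6.30-fold), and 32.7% the other way round (6.97-fold). Against the list of the other label, 43.2% of MCF7 H3K4me1 peaks (6.4-fold) and 48.7% of MCF7 H3K27ac peaks (8.21-fold) overlapped; the other way round, 13.6% of the list labelled H3K27ac overlapped MCF7 H3K4me1 (5.89-fold) and 41.3% of the list labelled H3K4me1 overlapped MCF7 H3K27ac (7.79-fold). The HCT116 lists have 35933 and 57632 peaks; 83.1% of the former overlapped the latter. All these had a permutation p of 0.000999, the smallest possible.

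Expression in siCONTROL differed with H3K27ac, H3K4me1 and H3K27me3 at gene starts. Genes with H3K27ac had a median of 14.9 against 0.0724 without it, and genes with H3K4me1 20.1 against 2.36. Genes with H3K27me3 had a median of 0.0550 against 4.75. For H3K9me3 the medians were 2.5 against 3.55, and 61.3% of genes with it and 59.3% without it were at 1 or more. It did not run in a single direction with expression: it marked 3.09% of genes under 0.01, 7.13% of the group with a median of 2.56, 1.54% of that with a median of 21.2 and 4.06% of the highest group. H3K27ac marked 2.70% of genes under 0.01 and 92.3% of the highest of 10 equal groups of the others, and H3K27me3 20.5% and 3.57%. Of 17596 genes, 253 had both H3K27ac and H3K27me3, with a median of 7.00, between 15.2 for H3K27ac without H3K27me3 and 0.0244 for H3K27me3 without H3K27ac. These are comparisons across genes, which are not independent replicates.

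**Figure D4:**
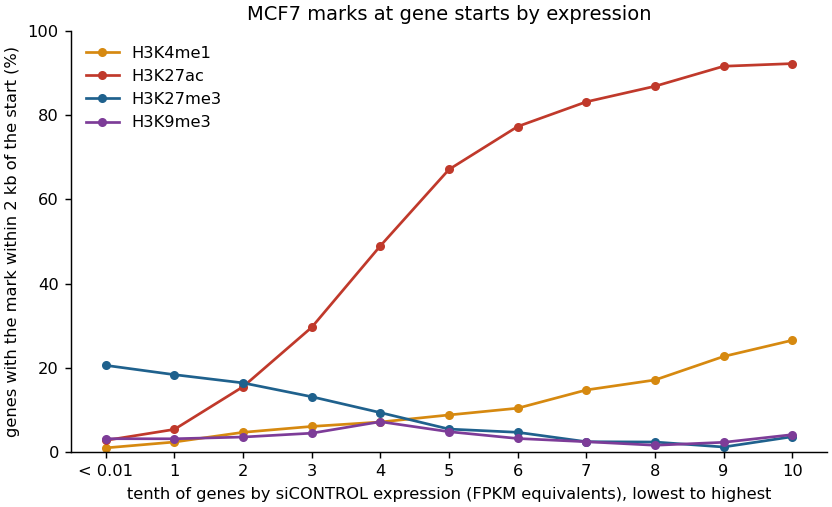
Share of genes with each MCF7 mark within 2 kb of the start, for genes under 0.01 FPKM equivalents and for 10 equal groups of the other genes by siCONTROL expression. H3K27ac rises from 2.70% to 92.3%, and H3K27me3 goes from 20.5% to 3.57%.

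Gene families differed in their repressive marks. H3K27me3 lay on 40.0% of developmental regulators such as HOX and PAX genes (24 of 60, Wilson interval 28.6 to 52.6%), against 16.3% of all genes, 4.56% of zinc finger genes and none of 14 reference genes. H3K9me3 lay on 70.5% of zinc finger genes (325 of 461, interval 66.2 to 74.5%), against 18.9% of all genes, 3.33% of developmental regulators and no reference gene. Both intervals treat genes as independent. Neighbouring genes can lie under a single wide peak, so the intervals may be too narrow. H3K27ac lay on 92.9% of reference genes, 65.9% of zinc finger genes and 26.7% of developmental regulators, against 58.6% of all genes. For H3K4me1 the shares were 42.9%, 10.8%, 6.67% and 24.3%.

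Most luminal breast genes carried active marks in MCF7. Within 10 kb, 24 of 25 luminal genes had MCF7 H3K27ac and 19 had H3K4me1, while 5 had H3K27me3 and 9 had H3K9me3. Of all genes tested with siGATA3, 86.1% had H3K27ac in that window, 37.3% H3K4me1, 10.6% H3K27me3 and 24.7% H3K9me3. ESR1 had 13 H3K4me1 and 12 H3K27ac peaks, and AGR2, AGR3, PGR, TFF1 and TFF3 had no peak in either HCT116 list. NAT1 had no active mark and 4 H3K27me3 peaks. Of 20 colon genes, 8 had MCF7 H3K27ac, 6 H3K4me1, 11 H3K27me3 and 6 H3K9me3, and 10 and 15 had a peak in the HCT116 lists labelled H3K4me1 and H3K27ac. The difference between lines was not tested: the HCT116 lists are longer, and the Wilson intervals overlap (21.9 to 61.3% for MCF7 H3K27ac, 53.1 to 88.8% for the list labelled H3K27ac). The intestinal factor CDX2 had 6 H3K27me3 peaks in MCF7 and 2 and 4 peaks in those HCT116 lists, and TSPAN8 had 8 H3K27me3 peaks in MCF7. For luminal genes the HCT116 counts were 17 and 19.

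The genes changed by siGATA3 were set against the MCF7 marks within 10 kb. H3K27me3 lay near 22.6% of the 248 genes that rose, against 12.1% in matched random lists, above all 10000 of them. H3K4me1 lay near 44% of them against 33.5% (percentile 99.98), and H3K9me3 near 31.5% against 25.4% (98.2). The random lists were matched on the mean of the 3 libraries, which holds the rise itself. H3K27me3 was more frequent at genes of low siCONTROL expression, so part of its excess near genes that rose may follow from this matching. Matching on siCONTROL alone was not run for marks. Of the 255 placed genes that fell, 79.2% had H3K27ac against 85.5% (0.205) and 16.1% had H3K27me3 against 10.6% (99.5). H3K4me1 near genes that fell (38.0% against 36.5%), H3K9me3 near genes that fell (20.8% against 24.7%) and H3K27ac near genes that rose (84.7% against 82.3%) lay inside the central 95%. MCF7 H3K27ac without the list labelled HCT116 H3K27ac lay near 10.1% of genes that rose and 7.84% of genes that fell, also inside it. H3K27ac without a peak of either HCT116 list lay near 7.66% of genes that rose against 4.44% (98.6), and near 3.14% of genes that fell against 3.53% (33.6). For siTCF7L2, 14 of the 15 genes that rose had H3K27ac and 7 had H3K4me1; of the 22 that fell, 20 had H3K27ac and none had H3K27me3, all inside the central 95%. H3K27ac without either HCT116 list lay near 4 of the 22 that fell, 18.2% against 4.55% in matched lists (percentile 99.4). Length-matched lists, chosen after the data were seen, left these placements for siGATA3 as they were. Other settings did not: within 50 kb and at 2-fold, H3K27ac (92.9 and 94.7%) and H3K27me3 (28.6 and 26.3%) near genes that fell lay inside the central 95%, and H3K4me1 near genes that rose was at 29.3% at 2-fold, also inside it.

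Chromosomes differed in their share of MCF7 peaks relative to both HCT116 lists. H3K4me1 peaks were scarcest on X (log2 -2.86), 22 (-2.60) and 18 (-2.21) and most frequent on 8 (1.00) and 15 (0.98). H3K27ac was lowest on 18 (-0.82) and 22 (-0.63) and highest on 21 (0.67). H3K9me3 was highest on 20 (1.51), where DOK5, ZNF217 and BCAS1 carry wide peaks, and lowest on 22 (-3.26). H3K27me3 was at -2.90 on 22 and 1.08 on X. These counts have no replicate spread.

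**Figure D5:**
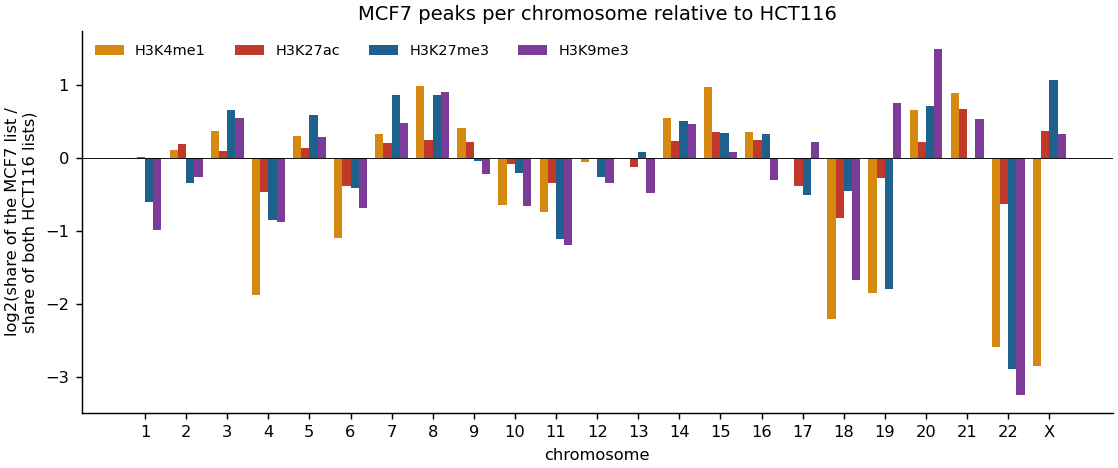
Log2 of the share of each MCF7 list on a chromosome over the share of both HCT116 lists there, for 23 chromosomes. H3K4me1 is at -2.86 on X, and H3K9me3 at 1.51 on 20 and -3.26 on 22.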

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

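The tests of the interferon pattern, the coverage test and the cell line test of the HCT116 lists, the test of chromosome X and the filter on siCONTROL alone were chosen after the results were seen; the others were written before.

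In the siGATA3 library the interferon list had a median log2 ratio of 1.86. The siCONTROL library was transfected too, so an effect of the transfection common to the libraries cancels in these ratios, and siTCF7L2 cannot test it. In siTCF7L2 the median was -0.0108, inside the central 95% of matched random lists, and -0.0862 with the filter on siCONTROL alone. The list thus did not rise above siCONTROL there. A response of RNA sensors to the GATA3 duplex (1.86 with the single duplex used) and the loss of GATA3, to 66.2% of control, cannot be told apart, since the series holds 1 duplex and 1 transfection. Both remain open hypotheses, and either may account for the rise.

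The HCT116 lists may carry each other's label: the source field of each names the other mark. Fold overlaps of the MCF7 lists with both HCT116 lists went with an exchange. MCF7 H3K27ac overlapped the list labelled H3K4me1 more (8.21-fold) than its namesake (6.30). MCF7 H3K4me1 overlapped the list labelled H3K27ac more (6.4) than its namesake (5.88). The list labelled H3K4me1 overlapped MCF7 H3K27ac more (7.79) than MCF7 H3K4me1 (5.52). The list labelled H3K27ac also overlapped MCF7 H3K27ac more (6.97) than MCF7 H3K4me1 (5.89). Both HCT116 lists thus favoured MCF7 H3K27ac, so this comparison within each list cannot tell the labels apart. The list labelled H3K4me1 had a share of peaks at gene starts 4.09 percentage points above that of the list labelled H3K27ac, the order seen for MCF7 H3K27ac over MCF7 H3K4me1, and its coverage ratio at the start was 3.20. Unequal list lengths do not account for it: with 20760 top-scoring peaks each, the share was 2.05 times that of the other list. A real difference between the lines in where the marks lie stays open, because the series has no other HCT116 list to set against the ratio of 0.615 in the list labelled H3K27ac. The exchange is a hypothesis.

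MCF7 peaks were unevenly spread over chromosomes relative to HCT116, with log2 shares for H3K4me1 of -2.86 on X, -2.60 on 22 and 1.00 on 8. Copy number could account for part of this: across 23 chromosomes the H3K27ac ratio followed the density of H3K27me3 peaks with r = 0.543 (permutation p 0.00954, adjusted 0.0191 over 4 relations; rho 0.482, permutation p 0.0221), but r was 0.326 without 18 and 22, so the relation rests on those chromosomes. For the H3K4me1 ratio r was 0.720 (rho 0.685; permutation p 0.0001 and 0.0004), and 0.663 without 22 and X. On X the other MCF7 marks stood above HCT116 (H3K27ac 0.38, H3K27me3 1.08, H3K9me3 0.328), so their ratios do not show a lower copy number there than in HCT116. Both HCT116 lists were sparsest on X (4.89 and 4.57 peaks per Mb), so a copy number low in both lines would not show in these ratios. The H3K27ac ratio did not follow gene density, with r of -0.136 (permutation p 0.531, and r of -0.309 without 18 and 22). An effect of gene density common to both lines cancels in this ratio, so such an effect was not tested. No copy number was measured, so copy number remains a hypothesis, and the cause on X stays open.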

How the results depend on the processing

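Leaving out overlapping genes, matching on gene length and filtering and matching gene lists on siCONTROL alone were chosen after the data were seen; all other alternatives were fixed before the data were examined. No called value changed sign, but the balance of called genes did turn. List medians kept their side of the threshold in 222 of 235 alternatives, overlaps between cell lines in 20 of 20, MCF7 overlaps in 42 of 48 and marks near changed genes in 89 of 108. Other results stayed the same in 135 of 184 alternatives for named genes, 19 of 21 for siRNA targets, 8 of 12 for the shared response, 23 of 28 for loci, 19 of 24 for families and 6 of 12 for marks and expression; gene counts did in 18, 15 and 18 of 22, and shares at gene starts moved in 20 of 20. The 2-fold rule was not run for marks near genes changed by siTCF7L2, with too few genes left. Where no construction is named below, the cause was not tested.

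Counts followed the rule's strictness. With a pseudocount of 0.1, 366 genes were higher and 393 lower with siGATA3, 40 and 30 with siTCF7L2, turning the balance of 15 and 22, and 395 and 426 in siTCF7L2 against siGATA3; 17 genes were shared in direction, the covariance was 0.0163 and TCF7L2 passed at -0.61; with 0.5, 26 genes were higher and 25 lower with siTCF7L2. Without a minimum, siGATA3 had 290 higher and 273 lower, against 248 and 256. At a minimum of 5, where fewer genes were tested, these were 151 and 190 with siGATA3, 7 and 15 with siTCF7L2 and 165 and 197 in the direct comparison. At 2-fold they were 75 and 19, 1 and 4, and 37 and 96 (higher and lower), 3 genes were shared, and GATA3 at -0.59 no longer passed. Without overlapping genes siTCF7L2 had 7 higher and 14 lower and 2 were shared. At a minimum of 5 with siTCF7L2, Wnt targets were at 0.0936, inside the range. Luminal and interferon genes were at -0.0814 and -0.0816, outside it. Filtered on siCONTROL alone, interferon genes were at -0.0862, also outside, and YAP targets at 0.0945, inside. With siGATA3 that filter put mammary secretory genes inside (0.203), and junction genes (0.112) and cholesterol synthesis genes (0.108) outside.

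H3K9me3 on H3K27me3 passed at 1.46-fold (50% overlap) and 1.54-fold (equal lengths). H3K9me3 on H3K4me1 no longer passed at 1.18 (upper-scoring part) and 1.27 (equal lengths), and H3K9me3 on H3K27ac passed at 0.786 and 0.815. Shares of peaks at gene starts, in the order MCF7 H3K4me1, H3K27ac, H3K27me3, H3K9me3 and the lists labelled HCT116 H3K4me1 and H3K27ac, were 4.32, 26.5, 3.51, 1.59, 29 and 20.2% within 1 kb, 16, 33.0, 7.88, 5.44, 36.9 and 32.3% within 5 kb, and 10.3, 38.2, 7.23, 3.58, 48.8 and 25.5% for upper-scoring peaks; exchanging the HCT116 lists gave 26.7 and 30.8%. Median expression of marked genes was 17.5 (H3K4me1) and 1.89 (H3K9me3) at 1 kb, 18.3 and 13.8 (H3K4me1, H3K27ac) at 5 kb, and 22.2 and 17.5 for upper-scoring peaks.

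Near genes that fell with siGATA3, H3K27ac was at 92.9% and H3K27me3 at 28.6% within 50 kb, and at 94.7% and 26.3% at 2-fold, all inside the range; H3K4me1 near genes that rose was at 29.3% at 2-fold. Within 2 kb, 3 luminal genes had H3K27me3 and 4 had H3K9me3. With upper-scoring peaks, H3K9me3 lay at 3 luminal and 2 colon genes, and the list labelled HCT116 H3K27ac at 8 colon genes. H3K27me3 on developmental regulators was 26.7% over the gene span alone. Upper-scoring peaks gave 5.86% (H3K4me1) and 46.4% (H3K27ac) of zinc finger genes, and 16.7% (H3K27ac) and 0% (H3K9me3) of developmental regulators. Depth limits genes near 1 FPKM equivalent. Apart from depth, the added 1 shrinks ratios at low values, as for TCF7L2 at 3.68 in siCONTROL and 2.38 in siTCF7L2.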

Other observations

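With siGATA3, p53 targets, hypoxia genes and mammary secretory genes lay above the central 95% of matched random lists, and the other lists given here lay inside it. Percentiles are in brackets. With the filter on siCONTROL alone, junction genes (98.5) and cholesterol synthesis genes (97.8) lay above it and mammary secretory genes inside it. Targets of p53 had a median log2 ratio of 0.15 (percentile 99.2), with cyclin G1 (CCNG1) higher, from 82.1 to 124, and 20 of 21 not passing. Cholesterol synthesis genes had 0.11 (96.7), with the sterol transfer gene STARD4 higher (0.75; it overlaps another gene). Hypoxia genes had 0.18 (98.5), with the aldolase ALDOC higher, from 9.37 to 19.7. Secretory genes of the mammary gland had 0.27 (97.7, 5 tested), with ELF5 higher (0.68). ELF5 was at 0.796 in siCONTROL, and with the filter on siCONTROL alone it dropped out. The median of the remaining 4 was then 0.203 (95.2), inside the central 95%. Stress genes had 0.04 (65.5), with ATF3 lower (-0.86), immediate early genes 0.08 (81.9), with MYC and FOS (-1.02) lower, and TGF-beta targets -0.10 (9.27), with CDKN2B lower (-0.81; it overlaps another gene). Developmental regulators had -0.13 (4.59), with LHX2 lower (-0.67). Junction genes had 0.10 (95.7), YAP targets 0.03 (55.3), GATA and FOX factors -0.08 (12.1), histone genes 0.05 (71.5), mesenchymal genes 0.07 (67.1), NF-kB genes 0.05 (57.7) and colon markers 0.13 (79.7), with none called. Reference genes had 0.01 (51.5), with the antigen-presentation gene B2M higher, from 282 to 436 (0.63).

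With siTCF7L2 the medians were 0.06 for TGF-beta targets (85.1), with TGFB2 higher (0.60; it overlaps another gene), and -0.02 for immediate early genes (29.9), with IER3 lower (-0.61). They were 0.24 for the 3 colon markers tested (99.4, above the central 95%), 0.08 for GATA and FOX factors (95), 0.04 for junction genes (89.7), 0.10 for NF-kB genes (87.8), 0.03 for mesenchymal genes (62.3), 0.01 for reference genes (71.0) and -0.00 for stress genes (40.5). They were -0.01 for mammary secretory genes (40.2), -0.01 for hypoxia genes (36.9), -0.01 for developmental regulators (33.5), -0.04 for histone genes (11.6), -0.05 for cholesterol synthesis genes (10.6) and -0.08 for Notch targets (6.63). Apart from TGFB2 and IER3, no member of these lists was called.

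Markers of other cells stayed low. Of 16 leukocyte markers, 15 were under 1 FPKM equivalent in every library, and CD68 was at 1.58 in siCONTROL and 1.99 in siGATA3. Of the stromal and endothelial markers, ACTA2 and COL6A3 were tested; COL6A3 was at 1.05 and 1.04, and ACTA2 is given above among basal markers.

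The list labelled HCT116 H3K4me1 scored highest in DLGAP1, PDP1 and NTSR1, and was widest at PCDH7 (149130 bp), at PALLD and DDX60L, and at BLID. The list labelled HCT116 H3K27ac scored highest at 18:106140-112259, in ABCC3 and in SEPTIN9, and was widest at ARHGAP18 (79950 bp), upstream of MKLN1, and at PALLD and DDX60L. The region near the start of chromosome 18 was also among the top-scoring peaks of MCF7 H3K27me3 and H3K9me3.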
